A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

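The series holds messenger RNA libraries of Saccharomyces cerevisiae grown in rich medium to mid-log phase at 30 °C, with 3 libraries for each of 4 HSF1 genotypes and 3 of wild type moved to 37 °C for 15 min. Per the labels' protocols, total RNA was taken with hot phenol, mRNA was selected on oligo(dT), and cDNA was made with random hexamers and a nick-translation second strand. No marking of strands is stated. The deposited FPKM values, 1 column per library, had been scaled by the authors per kilobase of gene length and by the reads counted in that library, as the values themselves show. Whether reads or fragments were counted is not given in the sources used here. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.1. The genome build, the annotation and any filter are not given in the sources used here, so no coordinates are printed. No batch, day or sequencing run is given in the labels, so none was modelled. The raw reads were not analysed here.

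All 15 columns were matched to libraries by the labels, and groups were taken from the labels alone. The table had 7126 genes, 346 of them at 0 in all libraries. Symbols, lengths and GC content came from the annotation of the R64 reference, which matched 6048 identifiers, and the other 1078 (for example tRNA and other RNA genes, named as in the table) kept their own. FPKM times gene length was a whole multiple of 1 constant per library for 99.2 to 99.3% of the single-exon genes, within 0.01 read, which gave whole reads and the reads per library printed in the report (median 20675392). A single read on a gene of 1 kb equals 0.0647 FPKM in the shallowest library and 0.0394 in the deepest. The 10 most abundant genes, ranked by reads, took 11.6 to 18.4% of a library's reads on genes of known length. Values close to 1 FPKM rest on few reads, and with 1 added before the log2 their fold changes are understated.

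The design, written before the data were examined, held a branch for read counts and a branch for normalized values. As the table holds FPKM, the second was used. Values were taken as log2(FPKM + 1) for the 6399 genes with at least 1 FPKM in at least 3 libraries. A linear model with a mean per group was fitted to all 15 libraries with limma 3.58.1 in R 4.3.3, with moderated t tests, a trend of the variance with mean level and 10 residual degrees of freedom. In each comparison p was adjusted by Benjamini-Hochberg over all tested genes, and genes with adjusted p under 0.05 were called changed. There were 9 comparisons. Each of the other 4 groups was set against wild type at 30 °C, the double mutant against each single mutant, the single mutants against each other, the double mutant against wild type at 37 °C, and the interaction of the 2 sites was tested. Counts of genes with groups that do not overlap took the values of single libraries. Other tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

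The genes named in the text followed a rule set beforehand. It named HSF1, and for each comparison with wild type, and for the double mutant against each single mutant, the 10 highest and 10 lowest fold changes among called genes with a mean of at least 10 FPKM and groups that do not overlap. In the other comparisons it named 5 each way, and for each list described up to 4 members with the largest change. It also allowed any Hsf1 target chaperone. Where fewer genes passed, all of them were named.

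The 27 gene lists were written by hand from general knowledge before the data were examined, except ribosomal proteins, taken by name pattern (132 genes). They covered Hsf1 target chaperones (21), heat genes shared by Hsf1 and Msn2/4 (12), Msn2/4 general stress (26), cytosolic Hsp70 (14), Hsp90 (14), mitochondrial chaperones (9), disaggregation (11), proteasome (32), unfolded protein response (14) and heat and stress regulators (13). For growth and metabolism there were ribosome biogenesis (53), glycolysis (18), trehalose and glycogen (17), respiration and the TCA cycle (38), hexose transporters (18 of 20 tested), Gcn4 amino acid synthesis (40), sulfur and methionine (23 of 24), phosphate (16), Aft1 iron (22 of 23), ergosterol (26), and histones and cell cycle (25). The rest were Yap1 oxidative stress (20), cell wall (20 of 21), pheromone and mating type (19), auxotrophic and selection markers (7 of 11) and mitochondrially encoded genes (8 found of 14, none tested). Lists overlap, and SSA4 for example stands in more than 1. Each was tested against all other genes with camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data, adjusted over the 26 lists.

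Alternatives set beforehand were scaling each library to the same 75th percentile (upper quartile), limma without the trend, no filter (6780 genes), a filter at 10 FPKM (5638 genes), a pseudocount of 0.1, the replicate number as a replicate block, a fit on the groups of the comparison alone, a log2 fold change of at least 1, and leaving out each library in turn. Added after seeing the data were fits without the 2 libraries labelled mNmC replicate 3 and 37 °C replicate 3 (8 residual degrees of freedom), also with upper-quartile scaling, with the replicate block and with 1 more library left out, and limma voom on the recovered reads (5775 genes). The fit was tested on simulated data with known changes. With all 15 libraries the fit recovered 25.4 to 32.8% of changes of 0.5 log2, 74.6 to 80.6% of 1 log2 and 97.0 to 98.5% of 2 log2 over the 4 comparisons with wild type. With 13 libraries these were 74.6 to 83.6%, 92.5 to 98.5% and 98.5 to 100%, and each simulated comparison had 7 to 10 false calls among 142 to 197. Overlaps of called genes were tested with a one-sided Fisher exact test, and 100 simulations gave what unchanged groups set against shared controls would show.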

Results

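Messenger RNA was sequenced from cultures of the budding yeast Saccharomyces cerevisiae in 15 libraries, with 3 biological replicates in each of 5 groups. The series concerns how genes driven by Hsf1, the transcription factor of the heat shock response, depend on contacts between Hsf1 and the chaperone Hsp70. Cells carried the wild-type HSF1 allele, an allele with the amino-terminal Hsp70 site mutated (mN), one with the carboxyl-terminal site mutated (mC) or one with both mutated (mNmC), all at 30 °C. The fifth group was wild type held at 37 °C for 15 min. The deposited values were FPKM. Whole reads recovered from them numbered 18335488, 20585328 and 25409519 in wild type at 30 °C and 23795299, 21172898 and 20689879 in mN. They numbered 20598775, 20675392 and 21414874 in mC, 15462618, 18683016 and 18856476 in mNmC and 18349570, 21435708 and 22596806 at 37 °C. At these depths 6445 to 6615 genes had a value above 0 in each library, and 6399 genes entered the tests. Below, fold changes are log2 values ± SE from limma with Benjamini-Hochberg adjusted p, and levels are mean FPKM ± SD. Beside counts for gene lists stand those adjusted over the list alone. How reads shared by near-identical paralogs such as SSA1 and SSA2, HSP82 and HSC82, PHO11 and PHO12 or pairs of ribosomal protein genes were assigned is not given in the sources used here.

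HSF1 mRNA, the transcript of the altered gene, differed between the genotypes. HSF1 (YGL073W) stood at 155 ± 2.97 FPKM in wild type at 30 °C (n = 3), at 101 ± 12.6 in mN (n = 3) and at 246 ± 15.5 in mC (n = 3). The mNmC libraries gave 52.1, 59.4 and, in the library labelled replicate 3, 149.9 FPKM. At 37 °C they gave 159, 148 and, in the library labelled replicate 3, 67.6 FPKM. With the labels as given, HSF1 did not pass the test in mN (-0.63 ± 0.36, adjusted p = 0.560) or mC (0.66 ± 0.36, adjusted p = 0.577). Nor did it pass in mNmC (-0.99 ± 0.36, adjusted p = 0.0610) or at 37 °C (-0.40 ± 0.36, adjusted p = 0.386). With the library labelled replicate 3 left out of mNmC and of 37 °C, HSF1 fell in mN (-0.63 ± 0.09, adjusted p = 0.00151) and in mNmC (-1.46 ± 0.10, adjusted p = 1.82e-06), and rose in mC (0.66 ± 0.09, adjusted p = 0.00195). It was the 1 gene of 6399 called lower in mN, higher in mC and lower in mNmC. The mutated sites lie in the coding sequence of HSF1, so its mRNA level is no check of the mutations.

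HIS3 (YOR202W), an enzyme of histidine synthesis, belongs to the list of auxotrophic and selection marker genes. It stood at 477 ± 34.2 FPKM in wild type (n = 3), 265 ± 73.4 in mN (n = 3) and 612 ± 19.3 in mC (n = 3). In mNmC it stood at 197 ± 2.95 without the library labelled replicate 3 (n = 2). Of that list, 2 rose, 4 fell and 1 did not pass in mNmC with 13 libraries (1 higher and 2 lower as labelled, 2 higher and 4 lower over the list alone, camera adjusted p = 0.00438, 0.0569 with estimated correlation). In mN, 1 rose, 2 fell and 4 did not pass (none as labelled, 1 higher and 3 lower over the list alone, camera adjusted p = 0.0160, 0.156 with estimated correlation), and in mC, 1 rose, 2 fell and 4 did not pass (none as labelled, 1 higher and 2 lower over the list alone, camera adjusted p = 0.0569).

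**Figure D1:**
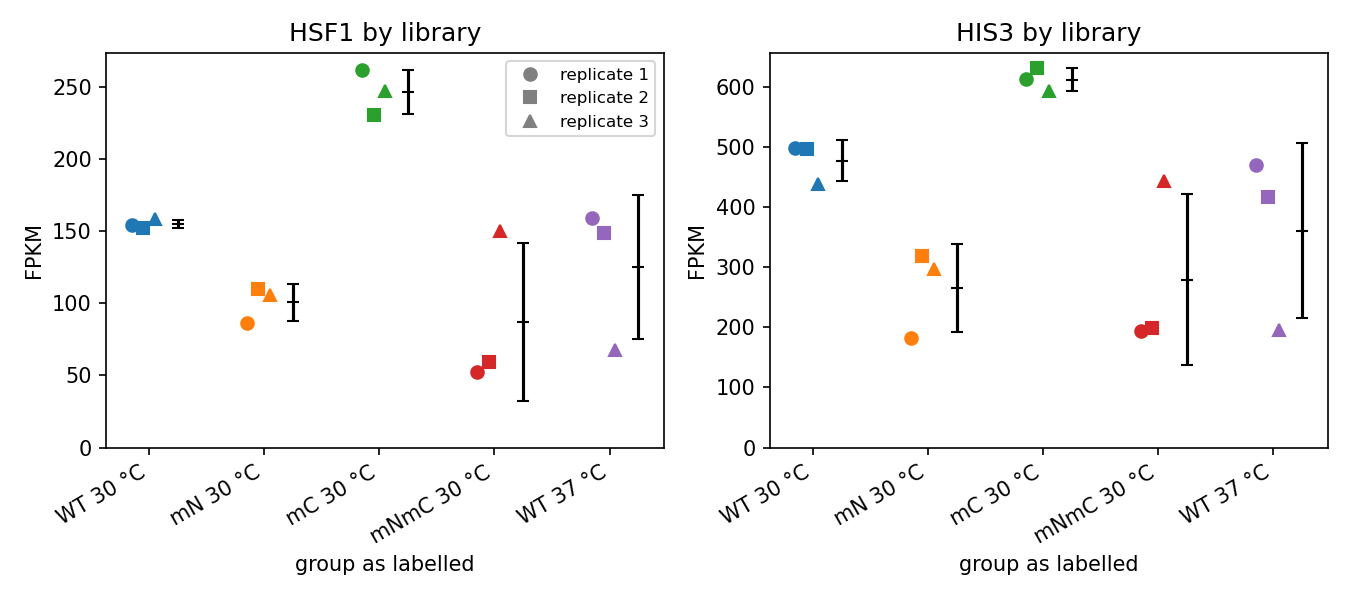
FPKM of HSF1 and HIS3 in each library, grouped as labelled, with points for libraries (circle, square and triangle for replicates 1, 2 and 3) and bars for the mean ± SD of the 3 libraries of a group. For HSF1, the triangle of mNmC lies at 149.9 FPKM, near wild type, and the triangle of 37 °C at 67.6, near the other two mNmC libraries.

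These 2 libraries also stood apart over all genes. Across genes, which are not independent replicates, the library labelled mNmC replicate 3 had a mean Spearman correlation of 0.921 with the other two mNmC libraries. With replicates 1 and 2 at 37 °C it had 0.997. The library labelled 37 °C replicate 3 had 0.918 with the other two libraries at 37 °C and 0.996 with replicates 1 and 2 of mNmC. CTT1 (YGR088W), the cytosolic catalase, read 21.4, 22.7 and 979.8 FPKM in mNmC replicates 1 to 3 as labelled, and 1003, 1009.8 and 20.4 FPKM at 37 °C. The groups were kept as labelled in the tests chosen before the data were examined. Counts of called genes are also given with 13 libraries, that is, without these 2, an alternative chosen after seeing the data, and gene lists are given in both ways or with 13 libraries, followed in brackets by the called genes as labelled. It also moved the counts of mN and mC, since the spread is pooled over all groups.

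**Figure D2:**
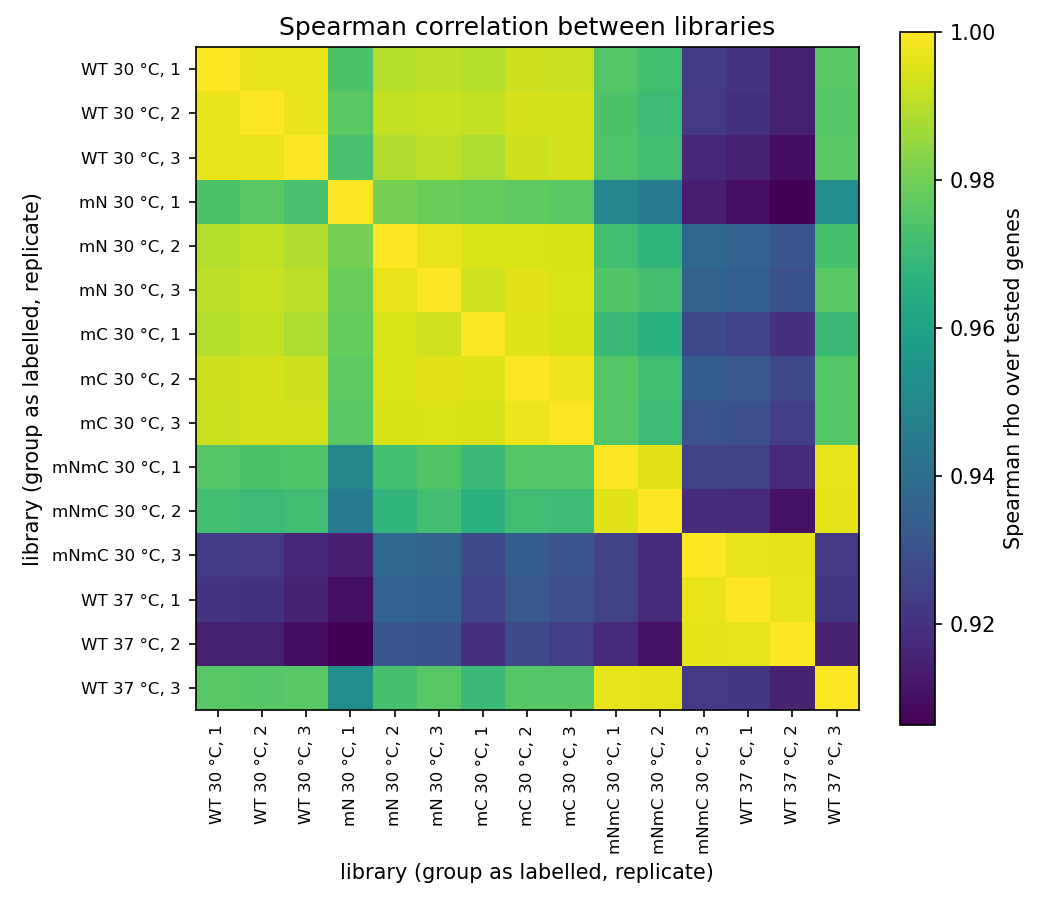
Spearman correlation across genes between each pair of the 15 libraries, ordered by labelled group, with colour for the coefficient. The library labelled mNmC replicate 3 correlates at 0.997 on average with replicates 1 and 2 at 37 °C, and the library labelled 37 °C replicate 3 at 0.996 with replicates 1 and 2 of mNmC.

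Wild type at 37 °C against 30 °C gives the heat shock response beside which the mutants are read. SSA4 (YER103W), the heat-inducible cytosolic Hsp70, rose by 4.71 ± 0.26, from 56.4 ± 2.08 FPKM (n = 3) to 1569.9 ± 539 (n = 3). The general stress genes HSP12 (YFL014W, 6.47 ± 1.38), a membrane-associated protein, and DDR2 (YOL052C-A, 4.14 ± 0.96) rose with it. So did ALD3 (YMR169C, 4.41 ± 1.48), an aldehyde dehydrogenase, CYC7 (YEL039C, 4.29 ± 0.85), a cytochrome c isoform, and SCR1 (4.37 ± 0.62), the RNA of the signal recognition particle. The other 4 of the 10 highest were EGO4 (YNR034W-A, 4.55 ± 1.15), PHO92 (YDR374C, 4.38 ± 1.14), YMR244W (4.15 ± 1.07) and YCL048W-A (4.15 ± 0.41). The agglutinin gene SAG1 (YJR004C, -2.92 ± 0.61) and the pheromone gene MF(ALPHA)2 (YGL089C, -2.35 ± 0.78) fell, and so did the leucine enzymes LEU1 (YGL009C, -2.87 ± 0.52) and BAT1 (YHR208W, -2.19 ± 0.47). Falls were also seen in the acid phosphatase PHO12 (YHR215W, -2.75 ± 0.43), the malic enzyme MAE1 (YKL029C, -1.99 ± 0.56) and INA1 (YLR413W, -2.03 ± 0.41). The ribosomal proteins RPL9A (YGL147C, -2.18 ± 0.78), RPL2A (YFR031C-A, -2.10 ± 0.36) and RPL29 (YFR032C-A, -2.00 ± 0.36) complete the 10 lowest. Adjusted p of these 20 genes ran from 3.68e-07 to 0.0455.

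The test called 2435 genes (2053 higher and 382 lower, 84.3% higher) as labelled, and 4217 genes (3008 higher and 1209 lower, 71.3% higher) with 13 libraries. Upper-quartile scaling moved the median of all genes from 0.26 to 0.04. With that scaling, 54.8% of 1905 called genes were higher as labelled and 53.3% of 4113 with 13 libraries. In 3450 of 6399 genes the 3 libraries at 37 °C did not overlap those at 30 °C, where chance gives 10%. Without the library labelled replicate 3 it was 5415 genes, where chance gives 20%. With 13 libraries the 20 changes named above were larger, except that of PHO12 (-2.35 ± 0.08), and rises there included HSP12 (8.25 ± 0.38), ALD3 (6.31 ± 0.10), CTT1 (5.92 ± 0.14) and HSP26 (YBR072W, 5.69 ± 0.18). The falls included SAG1 (-3.69 ± 0.17), LEU1 (-3.51 ± 0.09), MF(ALPHA)2 (-3.35 ± 0.19) and RPL9A (-3.17 ± 0.18).

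Chaperone and stress lists rose at 37 °C. Of the 21 Hsf1 target chaperones, 16 rose and 5 did not pass as labelled, and 18 rose and 3 did not pass with 13 libraries (list alone, 18 higher, then 18 higher). The camera test gave an adjusted p of 2.01e-07 as labelled (0.0321 with estimated correlation) and 3.07e-04 with 13 libraries (0.169 with estimated correlation). The largest changes with 13 libraries were those of HSP78 (YDR258C, 2.61 ± 0.13) and HSP104 (YLL026W, 2.38 ± 0.08), disaggregation factors of mitochondria and cytosol, HSP42 (YDR171W, 2.57 ± 0.13), a small heat shock protein, and HSP82 (YPL240C, 2.32 ± 0.13), the inducible Hsp90. Of 12 heat genes shared by Hsf1 and Msn2/4, the factors of the general stress response, 10 rose and 2 did not pass as labelled, and 12 rose with 13 libraries (list alone, 12 higher, then 12 higher). Camera's adjusted p was 2.00e-04 as labelled (0.343 with estimated correlation) and 1.10e-05 with 13 libraries (0.169 with estimated correlation). Of 26 Msn2/4 general stress genes, 17 rose and 9 did not pass as labelled, and 26 rose with 13 libraries (list alone, 25 higher, then 26 higher). By camera the adjusted p was 8.15e-04 as labelled (0.559 with estimated correlation) and 3.48e-13 with 13 libraries (0.169 with estimated correlation). Of 11 genes of disaggregation and sorting of misfolded protein, 10 rose and 1 did not pass as labelled, and 10 rose and 1 did not pass with 13 libraries (list alone, 10 higher, then 10 higher). For the list as a whole, camera gave an adjusted p of 1.28e-04 as labelled (0.0321 with estimated correlation) and 0.00186 with 13 libraries (0.169 with estimated correlation). Of 14 genes of cytosolic Hsp70 and its partners, 8 rose, 5 fell and 1 did not pass with 13 libraries, against 6 higher and 6 lower with upper-quartile scaling (7 higher and 3 lower as labelled, against 5 higher and 5 lower with upper-quartile scaling, 8 higher and 5 lower over the list alone, camera adjusted p = 0.895). In that list SSA3 (YBL075C, 3.24 ± 0.10), a stress-inducible Hsp70, rose and SSB1 (YDL229W, -1.78 ± 0.18), a ribosome-bound Hsp70, fell.

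Genes of the ribosome fell. Of 132 ribosomal protein genes, 1 rose, 59 fell and 72 did not pass as labelled, and 1 rose, 124 fell and 7 did not pass with 13 libraries (list alone, 1 higher and 113 lower, then 1 higher and 124 lower). Against all other genes, camera gave an adjusted p of 4.58e-36 as labelled (0.289 with estimated correlation) and 2.04e-53 with 13 libraries (0.105 with estimated correlation). RPL35A (YDL191W, -3.17 ± 0.56), RPS26B (YER131W, -2.97 ± 0.27) and RPL24A (YGL031C, -2.78 ± 0.12) were among the lowest. Of 53 ribosome biogenesis genes, 2 fell and 51 did not pass as labelled, and 50 fell and 3 did not pass with 13 libraries (list alone, none, then 52 lower). The camera test gave an adjusted p of 1.56e-11 as labelled (0.399 with estimated correlation) and 2.00e-22 with 13 libraries (0.128 with estimated correlation). They included GAR1 (YHR089C, -1.76 ± 0.18) and NOP7 (YGR103W, -1.73 ± 0.14). Of 26 ergosterol genes, 2 rose, 19 fell and 5 did not pass with 13 libraries (13 lower as labelled, 2 higher and 19 lower over the list alone, camera adjusted p = 1.33e-08, 0.0315 with estimated correlation), led by ERG3 (YLR056W, -1.38 ± 0.07) and ERG13 (YML126C, -1.28 ± 0.06). Of 25 histone and cell cycle genes, 2 rose, 14 fell and 9 did not pass (2 higher and 11 lower as labelled, 2 higher and 15 lower over the list alone, camera adjusted p = 6.26e-07, 0.169 with estimated correlation), the ribonucleotide reductase gene RNR1 (YER070W, -2.06 ± 0.09) and the G1 cyclin gene CLN2 (YPL256C, -1.94 ± 0.12) being the lowest.

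Genes of respiration and of storage carbohydrate rose. Of 38 genes of respiration and the TCA cycle, 35 rose and 3 did not pass with 13 libraries (31 higher as labelled, 36 higher over the list alone, camera adjusted p = 3.59e-07, 0.233 with estimated correlation), led by QCR10 (YHR001W-A, 2.44 ± 0.29) and QCR8 (YJL166W, 2.39 ± 0.20). Of 17 trehalose and glycogen genes, 16 rose and 1 fell (7 higher and 1 lower as labelled, 16 higher and 1 lower over the list alone, camera adjusted p = 1.40e-06, 0.169 with estimated correlation), led by the glycogen phosphorylase gene GPH1 (YPR160W, 4.61 ± 0.14) and the phosphoglucomutase gene PGM2 (YMR105C, 4.56 ± 0.11). Of 14 genes of the unfolded protein response, 14 rose (4 higher as labelled, 14 higher over the list alone, camera adjusted p = 1.87e-05, 0.0315 with estimated correlation), with MPD1 (YOR288C, 2.33 ± 0.10) and ULI1 (YFR026C, 2.30 ± 0.15). Hexose transporter genes split, as 12 rose, 4 fell and 2 did not pass (11 higher and 1 lower as labelled, 12 higher and 4 lower over the list alone, camera adjusted p = 0.369), and HXT5 (YHR096C, 4.88 ± 0.10) and HXT6 (YDR343C, 3.07 ± 0.18) rose most. Of 20 Yap1 genes of oxidative stress, 9 rose, 2 fell and 9 did not pass (5 higher and 1 lower as labelled, against 4 higher and 4 lower with upper-quartile scaling, 9 higher and 2 lower over the list alone, camera adjusted p = 0.424), the peroxiredoxin gene TSA2 (YDR453C, 3.10 ± 0.06) among the rises. Camera calls held with an estimated correlation for 2 of 26 lists as labelled, Hsf1 target chaperones and disaggregation. With 13 libraries they held for 2, the unfolded protein response and ergosterol synthesis, and for none once these were scaled to the upper quartile.

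The double mutant mNmC against wild type at 30 °C asks what mutation of both sites does without heat. SSA4 rose by 4.54 ± 0.26, from 56.4 ± 2.08 FPKM (n = 3) to 1392 ± 533 (n = 3), or 1084 ± 30.0 without the library labelled replicate 3 (n = 2). Other rises were YCL048W-A (3.59 ± 0.41), YEL073C (3.02 ± 0.29) and SPG4 (YMR107W, 2.94 ± 0.43). Higher too were SCR1 (3.59 ± 0.62) and the RNase P RNA RPR1 (2.91 ± 0.34), whose mature forms carry no poly(A) tail. The rises of HSP12 (5.06 ± 1.38), CYC7 (3.33 ± 0.85), DDR2 (3.06 ± 0.96) and YMR244W (3.11 ± 1.07) had wide errors, and each of these genes was far higher in the library labelled replicate 3 than in the other two. With 13 libraries they rose by 3.52, 2.43, 1.94 and 1.81. The acid phosphatase genes PHO12 (-3.16 ± 0.43) and PHO11 (YAR071W, -2.05 ± 0.44) fell, as did YHR214W-A (-1.76 ± 0.28) and YHR214W (-1.62 ± 0.24), open reading frames numbered beside PHO12. Falls of LEU1 (-2.26 ± 0.52), SAG1 (-2.12 ± 0.61) and BAT1 (-1.63 ± 0.47) were seen as at 37 °C, and were smaller with 13 libraries (-1.64, -1.43 and -1.08). The remaining 3 of the 10 lowest were RPL2A (-1.70 ± 0.36), RPL29 (-1.55 ± 0.36) and HUG1 (YML058W-A, -1.61 ± 0.42), a gene induced by DNA damage. Adjusted p of the 20 genes ran from 4.92e-07 to 0.0491. No strand-specific protocol is stated in the labels, so reads of overlapping genes were not separated here.

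The test called 1721 genes (1567 higher and 154 lower, 91.1% higher) as labelled, and 3071 genes (2598 higher and 473 lower, 84.6% higher) with 13 libraries. Upper-quartile scaling moved the median of all genes from 0.27 to 0.04, and then 60.7% of 1002 called genes were higher as labelled and 54.6% of 2381 with 13 libraries. In 3390 of 6399 genes the 3 mNmC libraries did not overlap wild type, where chance gives 10%. Without the library labelled replicate 3 it was 4953 genes, where chance gives 20%. With 13 libraries the rises were led by SSA4 (4.24 ± 0.09), HSP12 (3.52 ± 0.38) and BTN2 (YGR142W, 3.23 ± 0.11), a sorting factor for misfolded protein. Also high were NCE103 (YNL036W, 2.74 ± 0.35), the carbonic anhydrase, and SNZ1 (YMR096W, 2.64 ± 0.18), a gene of vitamin B6 synthesis.

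Chaperone genes rose together in mNmC. Of the 21 Hsf1 target chaperones, 18 rose and 3 did not pass as labelled, and 20 rose and 1 did not pass with 13 libraries (list alone, 21 higher, then 20 higher). Camera's adjusted p was 2.02e-10 as labelled (0.0134 with estimated correlation) and 4.09e-11 with 13 libraries (0.0302 with estimated correlation). As labelled, BTN2 (2.71 ± 0.41), HSP82 (2.51 ± 0.14), HSP42 (2.14 ± 0.23) and the J-protein gene SIS1 (YNL007C, 1.68 ± 0.15) rose. Of 14 genes of cytosolic Hsp70 and its partners, 9 rose, 1 fell and 4 did not pass with 13 libraries (8 higher as labelled, 9 higher and 1 lower over the list alone, camera adjusted p = 0.0114, 0.124 with estimated correlation), SIS1 (1.75 ± 0.14), FES1 (YBR101C, 1.68 ± 0.07) and SSA3 (1.58 ± 0.10) among them. Of 14 genes of Hsp90 and its cochaperones, 10 rose and 4 did not pass (8 higher as labelled, 10 higher over the list alone, camera adjusted p = 0.00438, 0.266 with estimated correlation), with the Hsp70 and Hsp90 adaptor STI1 (YOR027W, 1.69 ± 0.07). Of 11 disaggregation genes, 9 rose and 2 did not pass as labelled, and 10 rose and 1 did not pass with 13 libraries (list alone, 9 higher, then 10 higher). By camera the adjusted p was 2.49e-05 as labelled (0.0182 with estimated correlation) and 4.46e-05 with 13 libraries (0.0687 with estimated correlation). Of the 12 heat genes shared with Msn2/4, 9 rose and 3 did not pass with 13 libraries (7 higher as labelled, 10 higher and 1 lower over the list alone, camera adjusted p = 0.00333, 0.290 with estimated correlation). HSP26, a small heat shock protein of that list, stood at 238 ± 19.3 FPKM in mNmC (n = 2), against 169 ± 9.18 in wild type (n = 3) and 8781 ± 162 at 37 °C (n = 2).

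Of the 26 Msn2/4 general stress genes, 6 rose and 20 did not pass as labelled, and 16 rose, 1 fell and 9 did not pass with 13 libraries (list alone, 6 higher, then 16 higher and 1 lower). For the list as a whole, camera gave an adjusted p of 0.176 as labelled and 0.0187 with 13 libraries (0.540 with estimated correlation). CTT1 stood at 22.0 ± 0.909 FPKM in mNmC without the library labelled replicate 3 (n = 2), against 15.6 ± 1.17 in wild type (n = 3). Of 53 ribosome biogenesis genes, 1 rose, 1 fell and 51 did not pass as labelled, and 34 rose, 1 fell and 18 did not pass with 13 libraries (list alone, 1 higher, then 36 higher and 2 lower). Against all other genes, camera gave an adjusted p of 5.32e-05 as labelled (0.568 with estimated correlation) and 0.0196 with 13 libraries (0.564 with estimated correlation). The list pointed lower as labelled and higher with 13 libraries. Of 132 ribosomal protein genes, 1 rose, 2 fell and 129 did not pass as labelled, and 9 rose, 20 fell and 103 did not pass with 13 libraries (list alone, none, then 6 higher and 14 lower). The camera test gave an adjusted p of 1.95e-26 as labelled (0.306 with estimated correlation) and 6.15e-14 with 13 libraries (0.274 with estimated correlation). Their members went both ways, with RPL39 (YJL189W, 1.84 ± 0.50) up and RPL2A (-1.29 ± 0.14) down.

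Genes of the phosphate and iron regulons fell in mNmC. Of 16 genes of the phosphate regulon, 1 rose, 7 fell and 8 did not pass as labelled, and 2 rose and 14 fell with 13 libraries (list alone, 2 higher and 9 lower, then 2 higher and 14 lower). Camera's adjusted p was 2.91e-11 as labelled (0.131 with estimated correlation) and 2.13e-19 with 13 libraries (0.0103 with estimated correlation). The phosphate transporter PHO84 stood at 183 ± 39.1 FPKM (n = 2) against 976 ± 5.57 in wild type (n = 3), and SPL2 (YHR136C, -3.35 ± 0.26), PHO89 (YBR296C, -2.75 ± 0.25) and PHO11 (-2.60 ± 0.15) fell. Of 22 Aft1 genes of iron uptake, 2 rose, 7 fell and 13 did not pass as labelled, and 3 rose, 14 fell and 5 did not pass with 13 libraries (list alone, 3 higher and 7 lower, then 3 higher and 15 lower). By camera the adjusted p was 2.76e-07 as labelled (0.131 with estimated correlation) and 4.37e-13 with 13 libraries (0.0141 with estimated correlation). The cell wall mannoproteins of iron uptake FIT1 (YDR534C, -1.71 ± 0.28) and FIT2 (YOR382W, -1.41 ± 0.13) fell most. Of 20 cell wall genes, 15 rose, 1 fell and 4 did not pass with 13 libraries (13 higher as labelled, 16 higher and 1 lower over the list alone, camera adjusted p = 0.00333, 0.235 with estimated correlation), including KDX1 (YKL161C, 2.00 ± 0.10), a kinase paralog, and the mannoprotein CWP1 (YKL096W, 1.59 ± 0.12). Of 38 genes of respiration, 27 rose, 1 fell and 10 did not pass (13 higher as labelled, 28 higher and 1 lower over the list alone, camera adjusted p = 0.00227, 0.393 with estimated correlation), led by the citrate synthase gene CIT1 (YNR001C, 1.16 ± 0.07).

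Of 18 genes of glycolysis and fermentation in mNmC, 1 rose, 4 fell and 13 did not pass as labelled, and 2 rose, 10 fell and 6 did not pass with 13 libraries (list alone, 1 higher and 5 lower, then 2 higher and 10 lower). For the list as a whole, camera gave an adjusted p of 8.53e-07 as labelled (0.0389 with estimated correlation) and 8.65e-07 with 13 libraries (0.110 with estimated correlation). As labelled, the pyruvate decarboxylase gene PDC1 (YLR044C, -0.79 ± 0.15) fell and its paralog PDC5 (YLR134W, 0.95 ± 0.22) rose. Of 40 Gcn4 genes of amino acid synthesis, 2 rose, 6 fell and 32 did not pass as labelled, and 5 rose, 16 fell and 19 did not pass with 13 libraries (list alone, 2 higher and 6 lower, then 5 higher and 17 lower). Against all other genes, camera gave an adjusted p of 1.34e-10 as labelled (0.0389 with estimated correlation) and 8.17e-10 with 13 libraries (0.0222 with estimated correlation). Of 23 sulfur and methionine genes, 5 rose, 7 fell and 11 did not pass with 13 libraries, with a median of -0.15 under upper-quartile scaling (4 higher and 4 lower as labelled, 5 higher and 7 lower over the list alone, camera adjusted p = 0.00227, 0.0302 with estimated correlation, the test pointing lower with a median of 0.07 and a mean of -0.04), the methionine synthase gene MET6 (YER091C, -1.35 ± 0.09) being the lowest. Of 32 proteasome genes, 14 rose, 3 fell and 15 did not pass, against 2 higher and 3 lower with upper-quartile scaling (3 higher as labelled, against none with upper-quartile scaling, 14 higher and 3 lower over the list alone, camera adjusted p = 0.676), their activator RPN4 (YDL020C, 1.30 ± 0.13) rising most. Calls held with an estimated correlation for 4 of 26 lists as labelled (Hsf1 target chaperones, glycolysis, Gcn4 and disaggregation) and for 6 with 13 libraries (Hsf1 target chaperones, Gcn4, sulfur, phosphate, iron and ergosterol). With upper-quartile scaling they held for Hsf1 target chaperones and disaggregation as labelled, and for phosphate and disaggregation with 13 libraries.

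The mN mutant against wild type asks what follows mutation of the amino-terminal site alone. SSA4 rose by 2.03 ± 0.26, from 56.4 ± 2.08 to 234 ± 17.8 FPKM (n = 3 each), and HSP82 rose by 0.89 ± 0.14. Also higher were the general amino acid permease GAP1 (YKR039W, 1.53 ± 0.11), the ammonium permease MEP2 (YNL142W, 1.32 ± 0.16) and the urea amidolyase DUR12 (YBR208C, 1.25 ± 0.11). So were the cell wall gene PIR3 (YKL163W, 1.89 ± 0.13), the hexose transporter HXT4 (YHR092C, 1.60 ± 0.20), as well as YMR317W (1.05 ± 0.11) and ECM34 (YHL043W, 0.96 ± 0.16). The glutamate tRNA tE(UUC)K (2.84 ± 0.49) was the highest, with 54.3, 154 and 149 FPKM in the 3 libraries. The falls called were MET6 (-0.65 ± 0.11) and LAF1 (YMR102C, -0.41 ± 0.08). Adjusted p of these 12 genes ran from 1.71e-05 to 0.0390.

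In mN the test called 29 genes (27 higher and 2 lower) as labelled. With 13 libraries it called 1164 (821 higher and 343 lower, 70.5% higher). With upper-quartile scaling the 13 libraries gave 1320 genes, 60.4% of them higher. In 2208 of 6399 genes the groups did not overlap, where chance gives 10%. Without mN replicate 1, whose values deviated most from its group, the counts were 59 as labelled and 1887 with 13 libraries. Both fits give mN and mC the same fold changes over wild type and differ in the pooled spread. With 13 libraries that spread is pooled with groups less variable than mN. A fit of mN and wild type alone called 379. Among the 10 highest with 13 libraries were OPT2 (YPR194C, 2.52 ± 0.09), of the oligopeptide transporter family, and AGP1 (YCL025C, 1.38 ± 0.10), an amino acid permease.

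List counts in mN are given with 13 libraries. Of the 26 Msn2/4 genes, 17 rose and 9 did not pass (none as labelled, 20 higher over the list alone, camera adjusted p = 4.23e-10, 0.169 with estimated correlation), led by DDR2 (1.70 ± 0.06), GPH1 (1.63 ± 0.12) and YGP1 (YNL160W, 1.07 ± 0.08). Of the 21 Hsf1 target chaperones, 7 rose and 14 did not pass (7 higher over the list alone, camera adjusted p = 0.119). As labelled, 1 rose and 20 did not pass (1 higher over the list alone, camera adjusted p = 0.218). With 13 libraries HSP82 (0.89 ± 0.12), HSP78 (0.74 ± 0.12), BTN2 (0.63 ± 0.09) and HSP104 (0.54 ± 0.07) rose most among them. Of the ribosomal protein genes, 1 rose, 98 fell and 33 did not pass (none as labelled, 2 higher and 115 lower over the list alone, camera adjusted p = 5.31e-36, 0.156 with estimated correlation), including RPL35A (-1.61 ± 0.50), RPS29A (YLR388W, -1.19 ± 0.34) and RPL29 (-1.02 ± 0.22). Their median over wild type was -0.74, -0.52 and -0.33 in mN replicates 1 to 3, and in replicate 1 short genes read low. Of the histone and cell cycle genes, 1 rose, 12 fell and 12 did not pass (none as labelled, 2 higher and 12 lower over the list alone, camera adjusted p = 9.87e-07, 0.167 with estimated correlation), the histone genes HHF1 (YBR009C, -1.10 ± 0.14) and HTA2 (YBL003C, -1.05 ± 0.15) being lowest. Of the iron genes, 13 rose and 9 did not pass (1 higher as labelled, 15 higher over the list alone, camera adjusted p = 1.03e-06, 0.111 with estimated correlation), with the siderophore transporter ARN1 (YHL040C, 1.38 ± 0.09) and FIT3 (YOR383C, 0.97 ± 0.13). In the unfolded protein response list 11 rose and 3 did not pass (none as labelled, 11 higher over the list alone, camera adjusted p = 9.04e-06, 0.0438 with estimated correlation), including ULI1 (0.84 ± 0.13) and the ER Hsp70 gene KAR2 (YJL034W, 0.60 ± 0.16). Among the trehalose and glycogen genes 11 rose and 6 did not pass (none as labelled, 11 higher over the list alone, camera adjusted p = 8.91e-06, 0.169 with estimated correlation). Among the hexose transporter genes 4 rose and 14 did not pass (1 higher as labelled, 7 higher over the list alone, camera adjusted p = 0.00351, 0.156 with estimated correlation). As labelled, 8 lists were called by camera and none held with an estimated correlation. With 13 libraries 17 were called and 1 held, the unfolded protein response, which was lost with upper-quartile scaling.

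The mC mutant against wild type asks the same of the carboxyl-terminal site. Among genes called as labelled, chaperone genes were the highest, HSP82 (1.72 ± 0.14), SSA4 (1.57 ± 0.26) and STI1 (1.14 ± 0.09). HSP82 went from 149 ± 6.21 to 493 ± 32.7 FPKM and SSA4 to 169 ± 8.54 FPKM (n = 3 each). Other rises were BNA2 (YJR078W, 1.04 ± 0.18), an enzyme of NAD synthesis, the permease GAP1 (0.92 ± 0.11), the urea amidolyase DUR12 (0.66 ± 0.11) and the thiamine transporter THI7 (YLR237W, 0.65 ± 0.11). The type I myosin gene MYO5 (YMR109W, 0.42 ± 0.07) and UGX2 (YDL169C, 0.77 ± 0.12) rose as well. With 13 libraries EGO4 (2.29 ± 0.29) and OPT2 (1.78 ± 0.09) rose more than these. The 1 gene called lower was YKL102C (-0.81 ± 0.14), an open reading frame. Adjusted p of these 10 genes ran from 7.32e-05 to 0.0498. In mC the test called 12 genes (11 higher and 1 lower) as labelled. With 13 libraries it called 945 (788 higher and 157 lower, 83.4% higher). With upper-quartile scaling it called 6 genes as labelled and 729 with 13 libraries, 56.8% of them higher. Leaving out any 1 of the 6 libraries left 3 called genes (352 to 621 from 13). A fit of mC and wild type alone called 1866. In 2972 of 6399 genes the groups did not overlap, where chance gives 10%.

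Chaperone lists rose in mC. Of the 21 Hsf1 target chaperones, 2 rose and 19 did not pass as labelled, and 17 rose and 4 did not pass with 13 libraries (list alone, 16 higher, then 19 higher). The camera test gave an adjusted p of 5.64e-19 as labelled (9.04e-04 with estimated correlation) and 8.65e-17 with 13 libraries (0.0257 with estimated correlation). With 13 libraries, BTN2 (1.30 ± 0.09), HSP42 (0.96 ± 0.12) and the mitochondrial J-protein gene MDJ1 (YFL016C, 0.96 ± 0.17) rose among them. Of the cytosolic Hsp70 list, 9 rose and 5 did not pass (1 higher as labelled, 9 higher over the list alone, camera adjusted p = 8.53e-05, 0.0330 with estimated correlation), with SSA1 (YAL005C, 0.82 ± 0.10) and its exchange factor FES1 (0.82 ± 0.06). Of the Hsp90 list, 6 rose, 1 fell and 7 did not pass (2 higher as labelled, 6 higher and 1 lower over the list alone, camera adjusted p = 0.00295, 0.237 with estimated correlation). Of 9 mitochondrial chaperone genes, 5 rose and 4 did not pass (none as labelled, 5 higher over the list alone, camera adjusted p = 0.00215, 0.138 with estimated correlation), the chaperonin HSP60 (YLR259C, 0.62 ± 0.06) included. Of the disaggregation list, 7 rose and 4 did not pass (1 higher as labelled, 8 higher over the list alone, camera adjusted p = 1.83e-07, 0.0330 with estimated correlation). Of the Msn2/4 genes, 15 rose and 11 did not pass (none as labelled, 19 higher over the list alone, camera adjusted p = 2.46e-08, 0.201 with estimated correlation), led by DDR2 (1.31 ± 0.06) and PGM2 (1.02 ± 0.10). Of the ribosomal protein genes, 1 rose, 56 fell and 75 did not pass (none as labelled, 3 higher and 81 lower over the list alone, camera adjusted p = 3.32e-43, 0.109 with estimated correlation), RPL28 (YGL103W, -0.85 ± 0.20) and RPL36B (YPL249C-A, -0.78 ± 0.20) among them. As labelled, calls held with an estimated correlation for 2 of 26 lists, Hsf1 target chaperones and disaggregation. With 13 libraries they held for those 2, cytosolic Hsp70, the unfolded protein response, Gcn4 and ergosterol, and for those 2 alone with upper-quartile scaling.

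The double mutant against mN asks what the second mutated site adds. Higher in mNmC were SSA4 (2.50 ± 0.26), HSP12 (4.47 ± 1.38), NCE103 (2.70 ± 0.36) and CYC7 (2.92 ± 0.85). The rest of the 10 highest were YEL073C (3.31 ± 0.29), CPP3 (YDR034W-B, 3.02 ± 0.57), SCR1 (2.91 ± 0.62), SPG4 (2.55 ± 0.43), DPA10 (YLR307C-A, 2.45 ± 0.33) and RPR1 (2.43 ± 0.34). Iron uptake genes were lower, FIT1 (-2.38 ± 0.28), FIT3 (-2.15 ± 0.20), ARN1 (-1.69 ± 0.28) and ARN2 (YHL047C, -1.63 ± 0.11), the last pair being siderophore transporters. Lower as well were PHO12 (-2.38 ± 0.43), SAG1 (-2.08 ± 0.61), LEU1 (-1.70 ± 0.52), OPT2 (-1.86 ± 0.54) and tE(UUC)K (-2.98 ± 0.49), and the anaerobic cell wall gene DAN1 (YJR150C, -2.36 ± 0.44). Adjusted p of the 20 ran from 3.86e-06 to 0.0358. The library labelled mNmC replicate 3 carried part of some changes, as with 13 libraries HSP12 had 2.94 ± 0.38, CYC7 2.01 ± 0.29, SCR1 2.22 ± 0.12, SAG1 -1.40 ± 0.17 and LEU1 -1.08 ± 0.09. The test called 1455 genes (1284 higher and 171 lower, 88.2% higher) as labelled, and 3214 genes (2536 higher and 678 lower, 78.9% higher) with 13 libraries. Upper-quartile scaling moved the median from 0.25 to 0.01, and 51.0% of 1033 called genes were higher as labelled and 48.8% of 2761 with 13 libraries. Among the 21 Hsf1 target chaperones, 17 were higher and 4 did not pass as labelled, and 20 were higher and 1 did not pass with 13 libraries (list alone, 20 higher, then 20 higher). Camera's adjusted p was 3.31e-10 as labelled (0.0125 with estimated correlation) and 2.45e-10 with 13 libraries (0.0517 with estimated correlation). Of the iron genes, 2 were higher, 16 were lower and 4 did not pass with 13 libraries (2 higher and 9 lower as labelled, 2 higher and 16 lower over the list alone, camera adjusted p = 2.12e-16, 0.00964 with estimated correlation).

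Against mC, the same question was put to the amino-terminal site. Higher in mNmC were SSA4 (2.97 ± 0.26), NCE103 (3.13 ± 0.36), CYC7 (2.86 ± 0.85) and YKL102C (2.33 ± 0.14), with SCR1 (3.27 ± 0.62), RPR1 (2.60 ± 0.34), CPP3 (3.13 ± 0.57), DPA10 (2.89 ± 0.33), SPG4 (2.77 ± 0.43) and YCL048W-A (2.65 ± 0.41). HSF1 itself was lower (-1.65 ± 0.36), as were PHO12 (-2.85 ± 0.43), PHO11 (-1.71 ± 0.44), HUG1 (-2.17 ± 0.42), DAN1 (-1.93 ± 0.44) and LEU1 (-1.77 ± 0.52). Iron genes were again among the lowest, FIT3 (-1.80 ± 0.20), FIT1 (-1.76 ± 0.28) and ARN2 (-1.39 ± 0.11), beside RPL2A (-1.48 ± 0.36). Adjusted p of the 20 ran from 1.52e-06 to 0.0415. With 13 libraries CYC7 (1.95 ± 0.29), SCR1 (2.59 ± 0.12), LEU1 (-1.15 ± 0.09) and RPL2A (-1.07 ± 0.14) changed less. The test called 937 genes (792 higher and 145 lower, 84.5% higher) as labelled, and 2378 genes (1769 higher and 609 lower, 74.4% higher) with 13 libraries. Upper-quartile scaling moved the median from 0.16 to 0.01, where 56.9% of 712 called genes were higher as labelled and 50.3% of 2278 with 13 libraries. Among the 21 Hsf1 target chaperones, 11 were higher and 10 did not pass as labelled, and 15 were higher, 2 were lower and 4 did not pass with 13 libraries (list alone, 13 higher and 2 lower, then 18 higher and 2 lower). By camera the adjusted p was 0.00241 as labelled (0.159 with estimated correlation) and 5.77e-05 with 13 libraries (0.173 with estimated correlation). Of the cell wall genes, 14 were higher, 1 was lower and 5 did not pass with 13 libraries (9 higher as labelled, 14 higher and 1 lower over the list alone, camera adjusted p = 2.74e-04, 0.181 with estimated correlation), led by CWP1 (2.19 ± 0.12) and KDX1 (2.06 ± 0.10). As labelled, calls held with an estimated correlation for 3 lists against mN (Hsf1 target chaperones, glycolysis and disaggregation) and none against mC. With 13 libraries they held for the unfolded protein response, phosphate and iron in both comparisons. Upper-quartile scaling left none of these, and as labelled it ended the call of glycolysis.

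The single mutants against each other ask whether the sites differ. Chaperone genes were higher in mC than in mN, STI1 (0.98 ± 0.09), HSP82 (0.83 ± 0.14) and HSP60 (0.68 ± 0.11), beside the silencing deacetylase gene SIR2 (YDL042C, 0.51 ± 0.08). Lower in mC were tE(UUC)K (-3.01 ± 0.49), PIR3 (-1.30 ± 0.13) and YMR317W (-0.67 ± 0.11). The test called 10 genes (7 higher and 3 lower, 70.0% higher) as labelled, and 66 genes (29 higher and 37 lower, 43.9% higher) with 13 libraries. With upper-quartile scaling 33.3% of 9 called genes were higher as labelled and 31.5% of 108 with 13 libraries. Without mN replicate 1 the 13-library count was 148, and without mC replicate 3 it was 30. Of the 21 Hsf1 target chaperones, 3 were higher and 18 did not pass as labelled, and 11 were higher and 10 did not pass with 13 libraries (list alone, 13 higher, then 20 higher). For the list as a whole, camera gave an adjusted p of 2.15e-22 as labelled (4.39e-04 with estimated correlation) and 6.24e-24 with 13 libraries (0.0149 with estimated correlation). Of the cell wall genes, 3 were lower and 17 did not pass with 13 libraries (1 lower as labelled, 9 lower over the list alone, camera adjusted p = 8.04e-13, 0.0426 with estimated correlation). Calls held with an estimated correlation for 5 lists as labelled (Hsf1, Hsp90, mitochondrial chaperones, cell wall and disaggregation) and for 2 with 13 libraries (Hsf1 and cell wall), the latter lost with upper-quartile scaling.

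Non-additivity, the effect of mNmC over mC minus that of mN over wild type, asks whether the sites add up on the log2 scale. Above the sum of the single effects lay NCE103 (2.98 ± 0.51), CWP1 (2.63 ± 0.24), CPP3 (3.26 ± 0.81), DPA10 (2.89 ± 0.47) and YKL102C (2.47 ± 0.20). Below it lay OPT2 (-3.64 ± 0.76), DAN1 (-2.88 ± 0.62), FIT3 (-2.77 ± 0.28), FIT1 (-2.67 ± 0.40) and tE(UUC)K (-2.82 ± 0.69). FIT3 stood at 3608 ± 285 FPKM in wild type, 7141 ± 1258 in mN, 5579 ± 642 in mC and 1622 ± 365 in mNmC (n = 3 each). Adjusted p of the 10 ran from 2.60e-05 to 0.0397. The test called 300 genes (224 higher and 76 lower, 74.7% higher) as labelled, and 2237 genes (1417 higher and 820 lower, 63.3% higher) with 13 libraries. Upper-quartile scaling moved the median from 0.14 to -0.03, and 45.7% of 315 called genes were higher as labelled and 46.4% of 2364 with 13 libraries. Of the 21 Hsf1 target chaperones, 2 lay above the sum and 19 did not pass as labelled, and 12 lay above the sum and 9 did not pass with 13 libraries (list alone, 6 higher, then 14 higher and 1 lower). Against all other genes, camera gave an adjusted p of 0.148 as labelled and 0.00521 with 13 libraries (0.516 with estimated correlation). With 13 libraries CUR1 (YPR158W, 1.47 ± 0.20), MBF1 (YOR298C-A, 1.38 ± 0.20) and BTN2 (1.29 ± 0.14) lay highest, while HSP82 (-0.05 ± 0.18, adjusted p = 0.852) did not pass. Of the iron genes, 1 lay above, 18 lay below and 3 did not pass (1 higher and 7 lower as labelled, 2 higher and 18 lower over the list alone, camera adjusted p = 1.79e-13, 0.0114 with estimated correlation). Of the ribosomal protein genes, 100 lay above, 4 lay below and 28 did not pass (none as labelled, 107 higher and 5 lower over the list alone, camera adjusted p = 1.30e-11, 0.568 with estimated correlation). As labelled, none of 3 camera calls held with estimated correlation, and with 13 libraries 3 of 9 did, those of the unfolded protein response, phosphate and iron, and none with upper-quartile scaling.

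The double mutant at 30 °C against heat-shocked wild type asks how the mutant state differs from heat shock. As labelled, limma called 0 of 6399 genes, with 65 at an unadjusted p under 0.05. On recovered reads limma voom also called 0, with 37 at an unadjusted p under 0.05. In this comparison the library labelled replicate 3 of each group lay with the other group. With 13 libraries limma called 3637 genes (1794 higher and 1843 lower, 49.3% higher). Of the ribosomal protein genes, 128 were higher, 1 was lower and 3 did not pass in mNmC (128 higher and 2 lower over the list alone, camera adjusted p = 2.09e-35, 0.182 with estimated correlation), RPL35A (4.22 ± 0.61) and RPL9A (2.89 ± 0.20) leading. Of the ribosome biogenesis genes, 52 were higher and 1 was lower (52 higher and 1 lower over the list alone, camera adjusted p = 2.00e-19, 0.182 with estimated correlation). Of the Msn2/4 genes, 26 were lower (26 lower over the list alone, camera adjusted p = 5.12e-18, 0.175 with estimated correlation), CTT1 (-5.45 ± 0.15), ALD3 (-5.45 ± 0.11) and HSP12 (-4.73 ± 0.42) among them. Of the unfolded protein response genes, 14 were lower (14 lower over the list alone, camera adjusted p = 4.39e-08, 0.0129 with estimated correlation). The 21 Hsf1 target chaperones went both ways, as 8 were higher, 4 were lower and 9 did not pass (8 higher and 4 lower over the list alone, camera adjusted p = 0.189). Among them BTN2 (1.52 ± 0.12) and YDJ1 (YNL064C, 1.20 ± 0.08) were higher in mNmC and HSP78 (-0.94 ± 0.15) and HSP104 (-0.77 ± 0.08) lower, and HSP82 had 0.24 ± 0.14 (adjusted p = 0.179). As labelled, none of 10 camera calls held with estimated correlation, and with 13 libraries 1 of 14 did, the unfolded protein response, and none with upper-quartile scaling.

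Genes changed in mNmC overlapped those changed at 37 °C. As labelled, each group holds a library that lies with the other, which raises overlap and correlation. So labelled, 1348 were higher in both, 86.0% of 1567 in mNmC, against 503 for independent lists (log10 of the one-sided Fisher exact p, -598). In both, 136 were lower, 88.3% of 154, against 9.19 (one-sided Fisher exact p = 1.03e-155). No gene was called in opposite directions. With 13 libraries, 1612 were higher in both, 62.0% of 2598, against 1221 (one-sided Fisher exact p = 3.65e-89). There, 224 were lower in both, 47.4% of 473, against 89.4 (one-sided Fisher exact p = 3.83e-49), and 398 were called in opposite directions. Overlaps with upper-quartile scaling are given below. Across genes the fold changes had Pearson and Spearman correlations of 0.908 and 0.887 as labelled, and 0.423 and 0.387 with 13 libraries. Both comparisons share the wild type. In 100 simulations, unchanged groups with shared controls gave 0.501 and 0.461 as labelled and 0.404 and 0.370 with 13 libraries. They shared 0 called genes, so the correlation does not measure shared change. The covariance was 0.342, and 0.194 with 13 libraries, against 0.0364 and 0.0110 simulated. Separate controls were not tried, as there are 3.

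**Figure D3:**
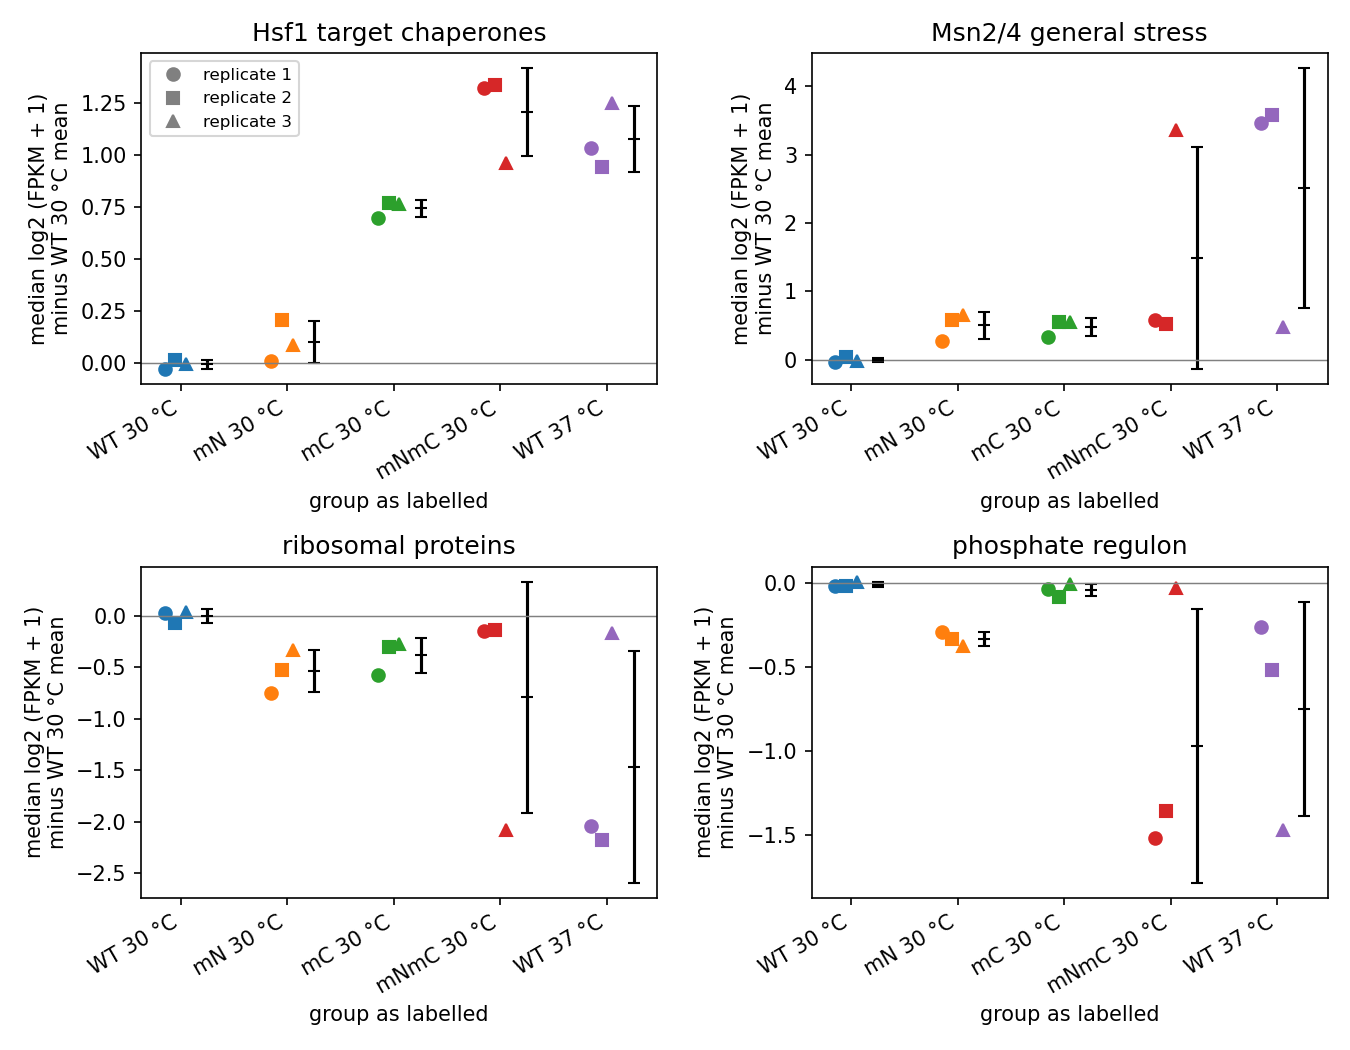
Median log2 fold change from the mean of wild type at 30 °C for 4 gene lists in each library, by group as labelled, with points for libraries (circle, square and triangle for replicates 1, 2 and 3) and bars for the mean ± SD of a group. In the Msn2/4, ribosomal protein and phosphate lists the triangle of mNmC lies nearer the other libraries at 37 °C, and the triangle of 37 °C nearer those of mNmC.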

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

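Tests on the 2 libraries that stood apart, on mN replicate 1 and on scaling, and all values with 13 libraries, were chosen only after the result was seen, and the splits of the libraries were set beforehand. The effects of the 2 mutated sites did not add up for 300 genes, by a test of the interaction itself. Those above the sum were led by CPP3 (3.26, 2.62 with 13), NCE103 (2.98, 2.87 with 13), DPA10 (2.89, 2.50 with 13), CWP1 (2.63, 2.53 with 13) and YKL102C (2.47, 2.50 with 13). OPT2 (-3.64, -4.25 with 13), DAN1 (-2.88, -3.44 with 13), tE(UUC)K (-2.82, -2.98 with 13), FIT3 (-2.77, -2.95 with 13) and FIT1 (-2.67, -2.91 with 13) lay furthest below it. Values are log2, first as labelled, and all 10 passed in both fits. The cell wall gene CWP1 stood at 276 ± 8.18 FPKM in wild type, 218 ± 27.1 in mN and 182 ± 9.95 in mC (n = 3 each), and at 839.8 ± 170.3 in mNmC without the library labelled replicate 3 (n = 2). OPT2 went the other way, with 15.5 ± 1.43, 93.3 ± 6.12, 55.5 ± 2.49 and 16.0 ± 0.372. Of 100 splits of the 12 libraries at 30 °C, the real one included and the others drawn at random, 1 gave as many as 300 genes, the highest other giving 172. This argues only against a random arrangement of libraries that do not differ. As the splits mix mNmC with other groups, they do not test additivity.

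The libraries labelled mNmC replicate 3 and 37 °C replicate 3 each lay with the other's group. The smaller of their 2 gaps in mean Spearman correlation, the other group minus their own, was 0.0751. A wild-type culture left unheated would lie with wild type on an axis of 610 genes that differ between mNmC and wild type and not at 37 °C, where wild-type libraries had slopes from -0.0556 to 0.0564, but the library labelled 37 °C replicate 3 had 0.878. A double-mutant culture under heat or another stress would keep the slope of the other double mutants (0.930 and 1.07), but the library labelled mNmC replicate 3 had 0.0415. These values argue against both, and an exchange of the labels of the 2 libraries is a candidate explanation, at a step that the tables do not show, while replacement of each by a library from outside the series was not tested.

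The library labelled mN replicate 1 stood apart from the other two mN libraries. The SD over genes of its log2 deviations from its group was 0.379, against 0.105 to 0.179 in the other 12 of 13 libraries. The median deviation of its shortest genes (at most 723 nt) minus that of its longest (at least 1863 nt) was -0.379, and the other 12 had at most 0.144 in size, so gene length may be part of the cause. After the trends with length and GC content were removed, its SD was still 0.331, so they are not the whole of it. Depth was not low, at 23795299 reads, and no biological explanation was tested, since the labels give none.

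More genes rose than fell in mNmC. With the library totals set to all reads, 91.1% of called genes were higher, and with upper-quartile scaling 60.7%. The 10 most abundant genes took 12.8 and 11.6% of the reads in mNmC replicates 1 and 2, against 14.6 to 15.5% in wild type. This would rescale the rest by 0.05 log2, against a median of 0.25 with 13 libraries. Since upper-quartile scaling brings the medians together by its construction, the lower share decides nothing. Scaling by the total and a change in mRNA per cell, which such values do not measure, stay open.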

How the results depend on the processing

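The tests without the 2 libraries that stood apart (with 13 libraries), alone, with another scaling, with the replicate block or with 1 more library left out, and the tests on recovered reads were chosen only after the result was seen. Among the named genes and the Hsf1 target chaperone list, HSF1 at 37 °C alone changed sign (-0.62 to 0.04 over libraries left out, not called there). The majority of called genes turned from higher to lower for mC against mN with 13 libraries (70.0% higher to 43.9%), with upper-quartile scaling (33.3%), with both (31.5%) and by voom on 13 (45.2%). With 1 more of the 13 left out the majority was lower without replicate 1 of mN (58 of 148 higher) or mC (28 of 61), and higher without replicate 2 or 3 of mN (27 of 48 and 34 of 60) or mC (20 of 39 and 16 of 30). It also turned for non-additivity with that scaling (74.7% to 45.7%, and 46.4% on 13), and for mNmC against mN with 13 so scaled (88.2% to 48.8%). At the preset correlation the Hsf1 target chaperone list was called in mC, mNmC and at 37 °C, and not in mN, under the alternatives tried, except that in mN it passed with 13 libraries when mN replicate 3 was also left out (median log2 fold change 0.15, 0.10 to 0.19 over such fits). With an estimated correlation it was lost at 37 °C with 13 libraries (adjusted p = 0.169) and with 13 scaled to the upper quartile (0.205), and in mNmC with the latter (0.0518). The counts of called genes stayed within 1.5 times the labelled ones without the trend, without a filter and with the pseudocount of 0.1. Where a value below moved, the cause was not tested, except that leaving out libraries or genes is itself a loss of data.

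Counts of called genes are given here where they moved by over 1.5 times. With 13 libraries they were mN 1164, mC 945, mNmC 3071, 37 °C 4217, mNmC against mN 3214, mNmC against mC 2378, mC against mN 66, mNmC against 37 °C 3637 and non-additivity 2237. Adding upper-quartile scaling gave mN 1320, mC 729, 37 °C 4113, mNmC against mN 2761, mNmC against mC 2278, mC against mN 108, mNmC against 37 °C 3778 and non-additivity 2364. Limma voom on recovered reads of 13 libraries gave mN 1209, mC 1019, mNmC 2984, 37 °C 3906, mNmC against mN 3097, mNmC against mC 2325, mC against mN 84, mNmC against 37 °C 3421 and non-additivity 2208, and voom on all 15 gave mC 5 and mC against mN 5. Upper-quartile scaling of all 15 gave mC 6 and mNmC 1002, and the filter at 10 FPKM mC 5. Fitting only the groups compared gave mN 379, mC 1866, mNmC against mN 161, mNmC against mC 341 and mC against mN 5. A log2 fold change of at least 1 left mN 8, mC 4, mNmC 394, 37 °C 729, mNmC against mN 301, mNmC against mC 222, mC against mN 5 and non-additivity 129.

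The replicate numbers did not pair the libraries. Of 30 pairs of equal number, 3 had deviations that correlated over 0.1 (-0.950 to 0.149), and with 13 libraries 4 of 23 did (-0.0490 to 0.149). The replicate block on 13 libraries gave 42.5% higher for mC against mN. With 15 the block moved the counts to mN 13, mC 3, mC against mN 3 and non-additivity 158, and with 13 libraries to mN 1246, mC 985, mNmC 3334, 37 °C 4288, mNmC against mN 3464, mNmC against mC 2684, mC against mN 73, mNmC against 37 °C 3715 and non-additivity 2458. With the replicate block on 13 libraries, 226 genes were lower in both mNmC and heat shock, the correlation of fold changes, mNmC and heat shock, was 0.424, and HSF1 stood at -0.63 in mN, 0.66 in mC and -1.44 in mNmC, each called. With an estimated correlation and the replicate block, the Hsf1 list was lost at 37 °C (adjusted p = 0.0518), and with 13 libraries at 37 °C (0.235), in mNmC (0.0991) and in mC (0.0671).

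Counts with 1 library of the comparison left out are given first from 14 libraries and in brackets from 12, where a group left with 1 library is assumed to vary like the other groups. The ranges were 8 to 59 (578 to 1887) in mN, 3 throughout (352 to 621) in mC, 983 to 1597 (1793 to 2690) in mNmC, 1146 to 3585 (3559 to 3938) at 37 °C, 872 to 1692 (1739 to 3483) for mNmC against mN, 409 to 1010 (1233 to 2166) against mC, 3 to 7 (30 to 148) for mC against mN and 97 to 547 (1427 to 2897) for non-additivity. For mNmC against 37 °C they were 0 throughout (2902 to 3160). In the wild-type comparisons each wild-type library left out (1, 2 and 3 in turn) moved the count by over 1.5 times, to 9, 9 and 8 in mN, 1024, 983 and 1083 in mNmC and 1418, 1347 and 1531 at 37 °C, and any of the 6 libraries gave 3 in mC. So did mN replicates 1, 2 and 3 in mN (59, 8 and 15) and 37 °C replicates 1 and 2 (1146 and 1210). For mNmC against mN, mN replicate 1 (881) and mNmC replicate 2 (872) did so, and against mC, mC replicates 1 and 2 (409 and 521) and mNmC replicate 2 (591). For mC against mN the libraries were mN replicates 2 and 3 (3 and 4) and each mC library (3). For non-additivity they were each wild-type library (97, 134 and 97), mN replicate 2 (142), each mC library (at most 184), mNmC replicates 1 and 2 (189 and 128) and the library labelled mNmC replicate 3 (547). With 13 libraries, mN moved by over 1.5 times without a wild-type library (578, 721 and 637) or mN replicate 1 (1887), mC without any of its 6 libraries (wild type 352, 459 and 458, mC 621, 503 and 486), and mC against mN without mN replicate 1 (148) or mC replicates 2 and 3 (39 and 30). Without mNmC replicate 2 as well, mNmC gave 1793, 1739 against mN, 1233 against mC and 1427 for non-additivity.

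The overlap of genes higher in mNmC and in heat shock was 543 with upper-quartile scaling and 762 with 13 libraries so scaled (755 to 1634 over single libraries left out). The overlap of genes lower in mNmC and in heat shock was 357 with that scaling, 224 with 13 libraries, 644 with 13 so scaled, 243 by voom on 13 and 77 in fits of the groups compared (64 to 190 over single libraries left out). The correlation of fold changes, mNmC and heat shock, was 0.423 with 13 libraries, 0.443 with 13 scaled to the upper quartile and 0.485 by voom on 13. Over single libraries left out it ran from 0.583 to 0.963, and from 0.399 to 0.434 when 13 were the start. Without the library labelled mNmC replicate 3 it was 0.583.

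HSF1 became a call in mN and mC with 13 libraries (-0.63 and 0.66) and with 13 scaled to the upper quartile (-0.62 and 0.58). So it did by voom on 13 (-0.63 and 0.67) and in fits of the groups compared (-0.63 and 0.66). In mNmC it became a call with upper-quartile scaling (-1.23), with 13 libraries (-1.46), scaled (-1.69), by voom on 13 (-1.48) and without the library labelled mNmC replicate 3 (-1.46), and at 37 °C only with 13 libraries scaled to the upper quartile (-0.26). Over single libraries left out, of 15 or of 13, HSF1 ranged from -0.69 to -0.52 in mN, 0.62 to 0.71 in mC and -1.55 to -0.71 in mNmC.

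Of the 202 results for single named genes (99 genes), none was lost with 13 libraries, and the 66 gained had been picked from that fit. Calls were lost in 20 results with upper-quartile scaling, 42 with the replicate block, 41 in fits of the groups compared, 26 by voom, 6 without the trend, 6 with the filter at 10 FPKM, 5 without a filter and none with the pseudocount of 0.1. With single libraries left out, each result was counted once per library of its comparison. Of these fits, 262 lost the call, 15 gained a call and 1001 did neither. Depth limits genes with few reads, and counts of reads alone do not set the spread seen between replicates.

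The 6 libraries of each comparison of 2 groups have 10 splits, too few for a share under 0.05. The real split gave 29 genes in mN, 12 in mC, 1721 in mNmC, 2435 at 37 °C, 1455 for mNmC against mN, 937 against mC and 10 for mC against mN, and the highest other split gave 0 in each, so 1 of 10 splits reached the real count. For mNmC against 37 °C all 10 reached the real count of 0, and the split of mNmC replicates 1 and 2 with the library labelled 37 °C replicate 3 against the rest called 4252, which points to a structure of the samples other than their labels.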

Other observations

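Genes and RNA classes in this part were chosen after their values were seen, as were all tests except that on the neighbours of HIS3, and values are with 13 libraries. Single genes of mating changed at 37 °C. The alpha-factor gene MF(ALPHA)1 (YPL187W) fell by 2.62 ± 0.14, as did the receptor gene STE3 (YKL178C, -2.15 ± 0.09), and MFA1 (YDR461W, 2.04 ± 0.22), MFA2 (YNL145W, 2.46 ± 0.29) and STE2 (YFL026W, 1.86 ± 0.15) rose. Those that rose began low, at 12.7, 19.9 and 9.04 FPKM in wild type, against 3779 for MF(ALPHA)1. Of the 19 pheromone and mating type genes, 8 rose, 6 fell and 5 did not pass at 37 °C, against 8 higher and 8 lower with upper-quartile scaling (8 higher and 7 lower over the list alone, camera adjusted p = 0.172). In mNmC, 5 rose, 6 fell and 8 did not pass (5 higher and 7 lower over the list alone, camera adjusted p = 0.00153, adjusted p = 0.290 with an estimated correlation). Of 13 heat and stress regulators, 10 rose and 3 did not pass at 37 °C (10 higher over the list alone, camera adjusted p = 0.0930), led by HAC1 (YFL031W, 1.64 ± 0.13) and RIM15 (YFL033C, 1.31 ± 0.09). In mNmC, 5 rose, 4 fell and 4 did not pass, against 4 higher and 5 lower with upper-quartile scaling (5 higher and 4 lower over the list alone, camera adjusted p = 0.148), with HAC1 lower (-0.92 ± 0.13).

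RNAs whose mature forms carry no poly(A) tail read highest at 37 °C, despite oligo(dT) selection. SCR1 read 31.7 to 34.4 FPKM in wild type, 44.8 to 60.5 in mN, 38.1 to 44.5 in mC, 252 and 261 in mNmC and 1246 and 1274 at 37 °C. RPR1 read 15.1 to 16.7 in wild type, 17.9 to 26.6 in mN, 17.8 to 21.8 in mC, 101 and 99.7 in mNmC and 245 and 242 at 37 °C, and NME1, the RNA of RNase MRP, 10.9 to 12.7, 9.86 to 16.1 and 11.4 to 13.7, then 23.8 and 20.3, then 89.6 and 104.6. The 299 tRNA genes together read 905 to 1097 in wild type, 1041 to 1455 in mN, 1219 to 1279 in mC, 1017 and 1117 in mNmC and 3458 and 3324 at 37 °C. The 81 snoRNA genes read 2275 to 2491 in wild type, 2019.7 to 2133 in mN, 2173 to 2294 in mC, 2809.5 and 2907 in mNmC and 3809 and 3843 at 37 °C. Class sums were not tested. In the library labelled mNmC replicate 3, SCR1 read 1069 and the tRNA genes 3407, and in that labelled 37 °C replicate 3, 226 and 1048. The marker genes URA3, LEU2 and LYS2 were listed at 0 in all 15 libraries, and of 14 mitochondrially encoded genes 8 were found and none passed the filter.

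HIS3 moved with HSF1 across the genotypes, at -0.88 (adjusted p = 0.00595) in mN, 0.36 (adjusted p = 0.175) in mC, which did not pass, and -1.27 (adjusted p = 2.99e-04) in mNmC. A HIS3 marker beside the HSF1 alleles would leave the neighbours of chromosomal HIS3 unmoved, as would any cause specific to HIS3. Of 6 limma tests of neighbours MRM1 (YOR201C) and DED1 (YOR204W), 0 were called in the direction of HIS3, and 1 (MRM1 in mC) had an unadjusted p under 0.05 that way. MRM1 had 0.02 (adjusted p = 0.933) in mN, 0.30 (adjusted p = 0.135) in mC and 0.39 (adjusted p = 0.0407) in mNmC, opposite to HIS3. DED1 had at most 0.04 in size. The cause stays open. More genes of the Gcn4 list, HIS3 included, fell than rose in mNmC. The alleles' marker and copy number are not given in the sources used here.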
